A study of Mus musculus with 2 samples.

How the data were processed

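RNA was extracted with a column kit and libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. The values are FPKM per gene, computed by the authors and deposited with gene identifiers, symbols, coordinates and gene lengths, per the file headers. The genome build is mm10, per the submitters' processing notes. The aligner, the counting method, strand handling, filters and the treatment of reads that match several genes are not given in the sources used here.

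Columns were tied to samples by name only. The column that carries the bare name of the cell line was taken as the authors' mean for the control group. A further 3 value columns have suffixes that match no label, so they were not mapped and were not used in any step. The co-culture group therefore had no mapped column. The comparisons fixed before the data were examined (genes higher and lower in co-culture, shifts of gene lists between groups) were not run, and no test between conditions was made. The rule for named genes fixed at that stage used the ratio of the groups, and only its last part could be kept, which names the housekeeping genes with Cdh1, Ptprc, Cd3e, Epcam and 1 gene that is not reported here. In its place the 4 highest members of each list and the 12 highest protein-coding genes outside the ribosomal, mitochondrial and predicted-gene classes were taken. This rule, and every other gene named, was chosen after values were seen.

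FPKM multiplied by gene length gave steps of 21.38, 23.16 and 23.23 in the low genes, and the column matched the equal-weight mean of 3 libraries with effective sizes of 15589461, 14389746 and 14350359 reads. Each value above 0 was searched for the whole reads in each library whose sum gives it within a relative tolerance of 1e-14. A single solution was found for 21364 of 21403 genes (99.8%). The other 39 genes, mostly with over 100000 reads, hold 16.3% of the length-weighted FPKM, and for these only the authors' mean is given. In lists with such genes the authors' mean stands in for library values in the medians. Of 300 decoy values per band of read number, none below 10000 reads had a solution, and on 5571 simulated genes the search was right in 100%. No decoys were run from 10000 reads upward, and many simulated genes had few reads. Library values of the most abundant genes were thus checked less. The total reads of a library were estimated from these reads and the unsolved genes. The libraries carry no labels and their numbers are arbitrary.

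Gene lists (38, fixed before the data were examined) were summarised by the median FPKM of their members and by the number at 1 FPKM or more. Differences between libraries were computed as log2(FPKM + 1) in a library minus the mean of the other 2. They cover genes with library values and an authors' mean of 1 FPKM or more. A list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, for lists with at least 5 such genes. This ranking describes these libraries and is not a test between conditions. On simulated data with 6000 genes, 3.9% of unshifted lists of 15 genes lay outside the central 95% and 100% of lists shifted by 0.5 did. The simulated genes varied independently, and the unshifted lists came from the pool they were ranked against. This checks the ranking procedure only and does not show how often real lists, whose genes may vary together, fall outside. Another 4 lists were added after values were seen. Shared sequence was measured as the percent of a gene's 31-base words (1 word in 8 positions) found in transcripts of another gene of GENCODE mouse release 21, which uses the same build. Of the gene identifiers, 99.9% matched that release, and 98.3% of those had identical start and end. Upper limits for genes at 0 reads correspond to 3 reads over the 3 libraries.

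Alternatives covered the pseudocount, the filter on low values, rescaling to a fixed total (TPM), other library sizes, the mean in place of the median, summed rows of 1 symbol and leaving out each recovered library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.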

Results

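Gene expression was measured by RNA sequencing in LA4 cells, a mouse lung epithelial line derived from a lung adenoma. The labels name 2 groups with 1 sample each. In the control group LA4 cells and lymphocytes were not cultured together, and in the co-culture group LA4 cells were kept with 10 lymphocytes per LA4 cell. The title places the work in asthma and in cell-in-cell structures, in which one living cell lies inside another. The deposited expression table held 1 value column that could be tied to a label. It is named for the cell line alone and was read here as the control, which its name supports but the labels do not state. The co-culture group had no column that its label identified, so the planned comparison of co-culture with control was not made. No gene is called changed by lymphocytes here. The values below describe the control column.

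The column holds the authors' mean FPKM, and its values resolved into whole reads of 3 libraries (called libraries 1, 2 and 3 here) with estimated totals of 15433058, 14380510 and 14313657 reads. The labels list the control as 1 sample, and nothing says whether the 3 libraries came from separate cultures. Their values are therefore given one by one or as a range, with no SD and no p-value. Of 54532 annotated genes, 21403 had a value above 0 and 11187 reached 1 FPKM, 9757 of them protein-coding. Genes at 0 reads have an upper limit set by 3 reads over the 3 libraries, which covers counting error only.

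In the control column, most markers of epithelium were at or near 0 beside high levels of several mesenchymal, contractile and matrix genes. Acta2, smooth muscle actin (mm10 chromosome 19, 34241090 to 34255336), was at 4835 FPKM, and Vim, the intermediate filament vimentin (chromosome 2, 13573927 to 13582826), was at 823 FPKM. Col1a1, Col1a2 and Col3a1, which encode fibrillar collagens, were at 474, 439 and 247 FPKM. Cdh1, the epithelial cadherin (chromosome 8, 106603351 to 106670246), had 5 reads over the 3 libraries (0.0254 FPKM). Epcam, an epithelial adhesion molecule (chromosome 17, 87635979 to 87651106), had 0 reads, which allows up to 0.0332 FPKM.

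Of the 18 epithelial markers, 16 were under 1 FPKM and 6 had 0 reads. The 6 were Epcam, Krt18, Ocln, Dsp, Esrp1 and Cldn3. The list median was 0.0254 FPKM, and in the libraries it was 0, 0.0312 and 0.00405 FPKM. The 2 markers above 1 FPKM were the junction proteins Jup at 13.4 FPKM (12.7 to 14.0 over the libraries) and Tjp1 at 11.4 FPKM (10.3 to 11.9). Among 15 alveolar markers, with a median of 0.0435 FPKM (0.0652 FPKM without library 2 or library 3), 6 reached 1 FPKM. Cav1 and Pdpn, which are not restricted to alveolar cells, were at 90.9 and 16.5 FPKM, and Abca3, a lipid transporter of surfactant-producing cells, was at 6.54 FPKM. Aqp5, Napsa and Ager were at 4.18, 1.79 and 1.13 FPKM. Sftpc, a surfactant protein, had 1 read, and Nkx2-1, the lung lineage transcription factor, had 0 reads, which allows up to 0.0238 FPKM.

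Of the 20 measured TGF-beta, mesenchymal and matrix genes, 13 reached 1 FPKM, with a list median of 6.28 FPKM (6.09, 6.63 and 6.12 in the libraries). They included the transcription factors Snai2 (12.2 FPKM), Snai1 (9.8 FPKM), Zeb1 (6.43 FPKM) and Twist1 (3.62 FPKM), and the cadherin Cdh2 (10.1 FPKM). Tagln, another contractile gene, was at 0.216 FPKM, with 60.9% of its 31-base words shared with other genes. On the log2(FPKM + 1) scale the median of this list lay 2.83 above that of the epithelial markers. The difference was 2.82, 2.89 and 2.82 in the 3 libraries. That range does not measure the spread over genes, and 7 of the 20 mesenchymal and matrix genes were under 1 FPKM. The size of the difference depends on the scale, with 5.67 for a pseudocount of 0.1, 1.17 for one of 5, and 4.11 after rescaling to a fixed total. Of 12 fibroblast and endothelial markers, 6 reached 1 FPKM. Pdgfrb, a receptor of fibroblasts and pericytes, was at 47.4 FPKM, whereas the endothelial genes Cdh5 and Kdr had 0 reads.

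**Figure D1:**
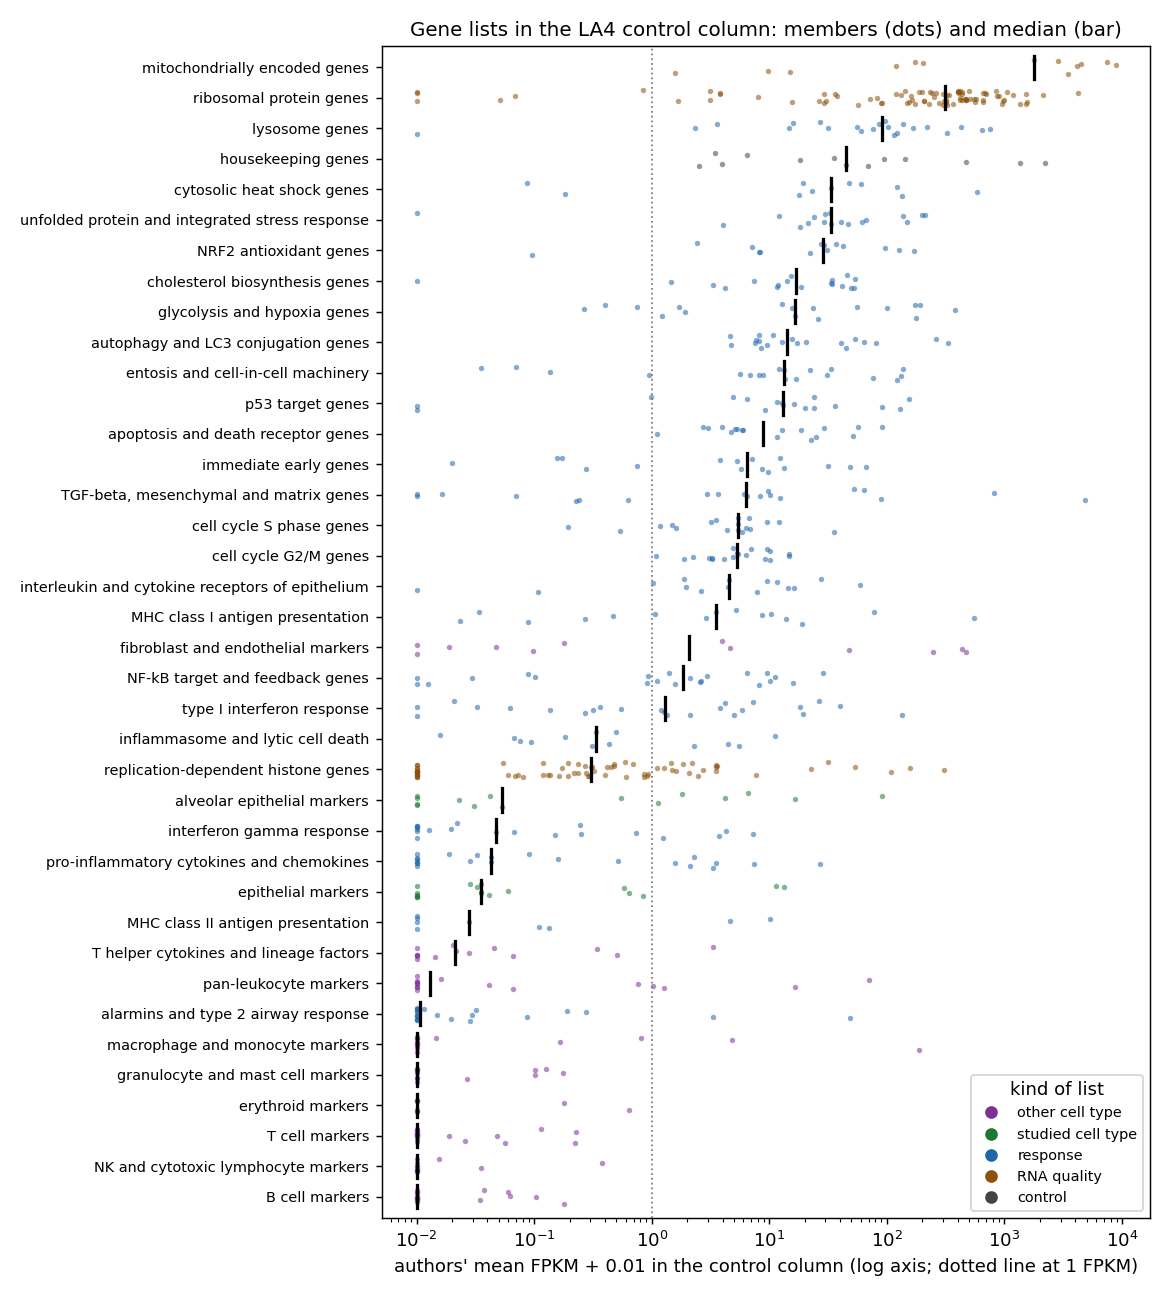
Each dot is a gene of 1 of 38 lists and each black bar the list median, on a log axis of the authors' mean FPKM plus 0.01 in the control column, coloured by the kind of list. Medians run from 0 FPKM in the T cell and B cell lists to 90.8 FPKM in the lysosome list and 1794 FPKM in the mitochondrially encoded genes, with the epithelial markers at 0.0254 FPKM.

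**Figure D2:**
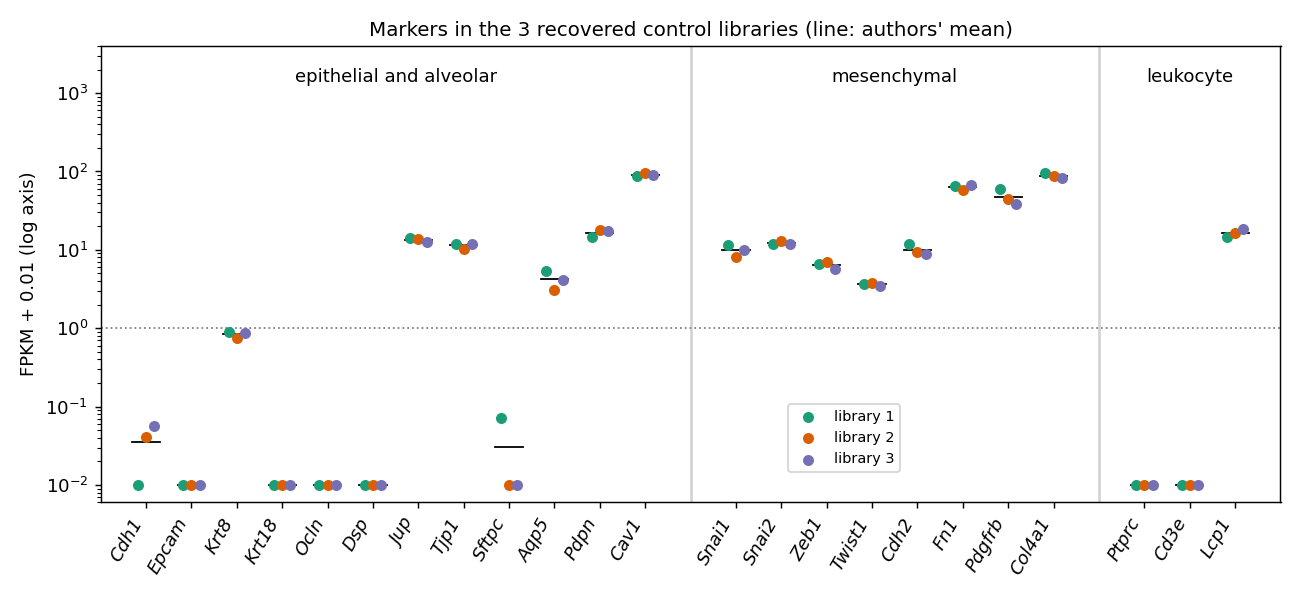
FPKM plus 0.01 on a log axis for named markers in each of the 3 recovered control libraries (coloured points), with the authors' mean as a line and a dotted line at 1 FPKM. Epcam, Krt18, Ocln, Dsp, Ptprc and Cd3e lie at 0 in all 3 libraries, whereas Cdh2 lies between 8.96 and 11.7 FPKM.

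Markers of lymphocytes were at the floor of the measurement. Ptprc, the pan-leukocyte antigen CD45 (chromosome 1, 138062861 to 138175708), and Cd3e of the T cell receptor complex (chromosome 9, 44998740 to 45009627) each had 0 reads. Those counts allow up to 0.00370 and 0.0166 FPKM. None of the 20 T cell and 16 B cell markers reached 1 FPKM. Both list medians were 0, and the 36 genes had 124 reads together. The highest of them was Trac, a T cell receptor constant segment, at 0.215 FPKM. The medians of the NK cell, granulocyte and erythroid lists were also 0, with no member at 1 FPKM.

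A few genes of leukocyte lists were present nonetheless. Of 16 pan-leukocyte markers, 4 reached 1 FPKM, and their list median was 0.00306 FPKM (0.00459 FPKM without library 1 or library 3, and 0 without library 2). Arhgdib was at 70.2 FPKM (62.2 to 79.6 over the libraries) and Lcp1, an actin bundler, at 16.5 FPKM. Of 14 macrophage markers, Cd68 was at 188 FPKM and Lyz2 at 4.78 FPKM, and the list median was 0. Among 14 T helper cytokines and lineage factors, with a median of 0.0111 FPKM (0 without library 1 or library 3), Il4 was the only one above 1 FPKM, at 3.30 FPKM. It had 181 reads, between 42 and 85 in each library.

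Lists of inflammatory genes differed in how many members were expressed in the control column. Of 22 cytokines and chemokines, 7 reached 1 FPKM, with a median of 0.0327 FPKM (0.0204 FPKM without library 2 and 0.0490 FPKM without library 3). Csf1, a macrophage growth factor, was highest at 26.7 FPKM, followed by Ccl7 at 7.36 FPKM, Cxcl5 at 3.54 FPKM and Cxcl1 at 3.33 FPKM. Tnf and Il1b had 0 reads and Il6 had 1 read. Of 22 NF-kB target and feedback genes, 14 reached 1 FPKM (median 1.83 FPKM), led by Nfkb2 at 28.7 FPKM and Nfkbib at 15.8 FPKM. In the list of alarmins and type 2 airway response, 2 of 22 genes reached 1 FPKM (median 0.000776 FPKM, and 0 without library 1 or library 3). These were Stat6, the transcription factor downstream of interleukin 4 and 13, at 49.0 FPKM, and the receptor chain Il4ra at 3.31 FPKM. Il33 and Muc5ac had 0 reads, and Tslp was at 0.181 FPKM.

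Of 24 type I interferon response genes, 14 reached 1 FPKM, with a median of 1.30 FPKM. Ifit3 was at 135 FPKM, although 55.6% of its 31-base words also occur in other genes. Isg15 was at 40.2 FPKM, Bst2 at 26.7 FPKM and Ifit2 at 19.2 FPKM, and Ifnb1 had 0 reads. The interferon gamma list had 4 of 19 genes at 1 FPKM (median 0.0371 FPKM, 0.0142 FPKM without library 2 and 0.0557 FPKM without library 1), with Irf1 at 7.24 FPKM. In MHC class I presentation, 10 of 15 genes reached 1 FPKM (median 3.49 FPKM). B2m, the invariant light chain, was at 548 FPKM, whereas the heavy chains H2-K1 and H2-D1 were at 8.66 and 1.06 FPKM, with 26.2% and 25.2% of their 31-base words shared. MHC class II presentation had 2 of 9 genes at 1 FPKM (median 0.0181 FPKM, and 0 without library 1 or library 2), H2-DMa at 10.1 FPKM and Cd74 at 4.61 FPKM. Among 15 cytokine receptors, 13 reached 1 FPKM (median 4.52 FPKM), led by Il17rc at 59.2 FPKM and Il6st at 27.4 FPKM.

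Genes of the machinery of entosis, the invasion of one cell into another, were mostly expressed. Of 19 genes, 15 reached 1 FPKM, and the median was 13.4 FPKM (12.9, 13.9 and 12.7 in the libraries). The adhesion link Ctnna1 was at 136 FPKM, the myosin heavy chain Myh9 at 132 FPKM, Cdc42 at 121 FPKM and Ctnnb1 at 76.4 FPKM. Rhoa and its kinases Rock2 and Rock1 were at 33.3, 13.5 and 12.1 FPKM. The 4 members under 1 FPKM were Cdh1, Cdh3 (0.125 FPKM), Myl9 (0.0600 FPKM) and Lpar2 (0.945 FPKM).

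All but 1 of the autophagy and lysosome genes reached 1 FPKM. All 20 autophagy and LC3 conjugation genes reached 1 FPKM (median 14.1 FPKM), with Gabarap at 328 FPKM and the cargo receptor Sqstm1 at 263 FPKM. Of 22 lysosome genes, 21 did so (median 90.8 FPKM), with Cd63 at 747 FPKM and Lamp1 at 647 FPKM, and Ctsh had 0 reads. All 18 apoptosis and death receptor genes reached 1 FPKM (median 8.84 FPKM), led by Bax at 91.5 FPKM and Tnfrsf1a at 56.6 FPKM. The inflammasome and lytic death list had 4 of 13 genes at 1 FPKM (median 0.325 FPKM). The necroptosis effector Mlkl was at 11.2 FPKM and Gsdmd at 5.48 FPKM, whereas Nlrp3 was at 0.00571 FPKM and Pycard at 0.0652 FPKM.

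Lists of stress and metabolic genes had medians between 6.43 and 33.6 FPKM. The unfolded protein and integrated stress response list had a median of 33.4 FPKM, with Hspa5 at 212 FPKM, Ddit3 at 147 FPKM and Atf4 at 136 FPKM. Cytosolic heat shock genes had a median of 33.6 FPKM, NRF2 antioxidant genes 28.5 FPKM, cholesterol biosynthesis genes 16.8 FPKM, and glycolysis and hypoxia genes 16.6 FPKM. p53 target genes had a median of 13.1 FPKM, with Ccng1 at 154 FPKM and Phlda3 at 130 FPKM, and immediate early genes one of 6.43 FPKM. Cell cycle genes of S phase and of G2/M had medians of 5.37 and 5.35 FPKM, led by Pcna at 35.5 FPKM and Ube2c at 14.8 FPKM. The highest protein-coding genes outside the ribosomal, mitochondrial and predicted-gene classes were Fth1 at 6294 FPKM, Eef1a1 at 4854 FPKM, Acta2, Eef2 at 2950 FPKM, Ftl1 at 2636 FPKM and Thbs1 at 2420 FPKM.

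Levels of some single genes were low for their role. All 13 housekeeping genes reached 1 FPKM with a median of 45.1 FPKM, among them Actb at 2233 FPKM, Ppia at 468 FPKM and Hprt at 68.7 FPKM. Gapdh, a glycolytic enzyme, was at 3.91 FPKM, and 32.5% of its 31-base words occur in other genes. The ribosomal protein genes had a median of 310 FPKM, whereas Rpl26 was at 3.15 FPKM and Rpl35a at 3.82 FPKM. Among the mitochondrially encoded genes (median 1794 FPKM), mt-Co1 was at 8813 FPKM and mt-Co3 at 172 FPKM. The list of replication-dependent histone genes, drawn by symbol, had a median of 0.296 FPKM, with 21 of 71 at 1 FPKM. Its highest member, H1f0 at 308.5 FPKM, is not replication-dependent, and Hist3h2bb-ps is a pseudogene. The libraries were made with an mRNA-Seq kit, and how far the kit captures histone transcripts was not tested.

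The 3 libraries differed from one another in whole gene groups, with list medians between -0.55 and 0.68 on the log2(FPKM + 1) scale. Cholesterol biosynthesis genes were lower in library 3 in 17 of 17 genes. The median difference from the mean of the other 2 libraries was -0.55 on the log2(FPKM + 1) scale, below all 10000 random lists matched on expression. In the same library, histone genes were higher in 17 of 21 (median 0.27) and mitochondrially encoded genes in 4 of 5 (median 0.68). Both lists were fixed as measures of RNA quality, but the histone genes moved with the cell cycle lists given below. These were all higher in library 3 and lower in library 1 (histone median -0.14). Only 5 of 13 mitochondrially encoded genes had library values, and genes with over 100000 reads had none. The members with the most reads were thus left out, so the shifts of these 5 do not describe mitochondrially encoded RNA as a whole. The SD over those 5 genes was 0.79 in library 3. Hmgcs1, the enzyme that makes hydroxymethylglutaryl-CoA, was at 49.6, 57.7 and 31.1 FPKM in libraries 1, 2 and 3, and Idi1 at 9.22, 8.64 and 4.47 FPKM. Type I interferon response genes were higher in library 2 in 13 of 14 genes, by a median of 0.39, and lower in library 3 in 11 of 14 (median -0.38). Isg15 was at 35.5, 58.0 and 27.1 FPKM. G2/M genes were higher in library 3 in 19 of 19 genes (median 0.25), and S phase genes in 14 of 16 (median 0.32). Both were lower in library 1, G2/M genes in 18 of 19 (median -0.24) and S phase genes in 14 of 16 (median -0.22). Ribosomal protein genes were lower in library 1 in 63 of 79 genes (median -0.26) and higher in library 2 in 56 of 79 (median 0.23). The 5 mitochondrially encoded genes with library values were lower in library 1 in 5 of 5 (median -0.55). The directions named here were the same with library sizes from total reads, median of ratios and upper quartile, although these left the median of all genes in library 3 within 0.0124 of 0.

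Of 72 pairs of list and library, 22 lay outside the central 95% of random lists, where random lists would give 3.6. The 3 values of a list are not independent of each other. Genes of a list may also vary together, which random lists do not reproduce, so the excess over 3.6 is a description and not a test. Lists of entosis machinery, autophagy, apoptosis, and TGF-beta, mesenchymal and matrix genes lay inside the central 95% in each library. The collagen and matrix crosslinking list, chosen after values were seen, lay outside it, at -0.17 in library 3 and 0.14 in library 1. Genes without library values were left out. The collagen list thus used 13 of its 20 genes at 1 FPKM or more, and the TGF-beta list 11 of 13. Over 7745 genes with 100 to 3000 reads, the median chi-square between libraries was 5.34 times that of counting noise. Counting noise takes reads as independent, so this ratio does not separate library preparation from differences between cells. Among 6982 genes with at least 1000 reads the median ratio of the highest to the lowest library was 1.18. Across 11148 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.973 between libraries 1 and 2, 0.982 between 1 and 3, and 0.978 between 2 and 3.

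**Figure D3:**
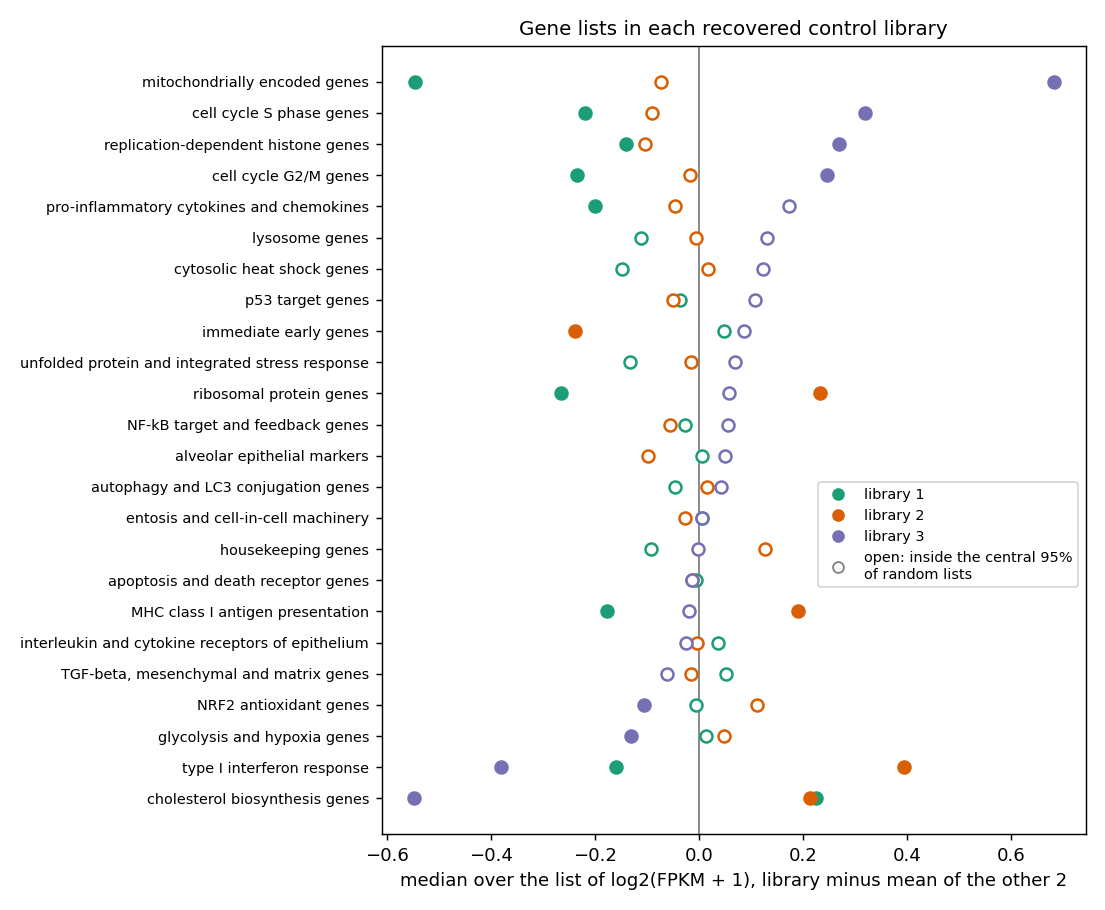
Median over each gene list of log2(FPKM + 1) in 1 library minus the mean of the other 2, for 24 lists. Each list has at least 5 genes at 1 FPKM with library values, and filled points lie outside the central 95% of random lists. The cholesterol list lies at -0.55 in library 3 and the interferon list at 0.39 in library 2. The largest value is 0.68 in library 3 for 5 of 13 mitochondrially encoded genes, without the members with the most reads.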

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

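The planned comparison of co-culture with control and its alternatives could not be computed, since no co-culture column was mapped. All alternatives below were chosen after seeing the data, except the summing of rows that share a symbol. No paired analysis was possible because the control column alone was mapped. The 11187 genes at 1 FPKM or more became 21403 with no filter on low values and 7129 at 5 FPKM or more, by construction of the filters, and stayed within 1.5 times under the other settings. The difference of 2.83 between the matrix and epithelial medians kept its direction throughout. It was 5.67 with a pseudocount of 0.1, 1.17 with one of 5, 4.11 after rescaling to a fixed total, and 4.41 after rescaling without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, since a pseudocount compresses low values. It was 2.71 with list means and 3.18 over members with under 10% shared 31-base words, and the cause was not tested. Without 1 library in turn it ranged from 2.80 to 2.85. Of 37 list medians, 6 moved over 1.5 times without 1 library, each of them at or under 0.0371 FPKM, and that of the alveolar markers rose by 1.5 times to 0.0652 FPKM. With 23 of 36 T cell and B cell markers at 0 reads their median cannot move, and their mean went from 0.0294 to 0.0816 FPKM after rescaling to a fixed total. The cholesterol difference in library 3 was -0.33 with a pseudocount of 5, which compresses it, and stayed within 1.5 times of -0.55 otherwise. The spread ratio of 5.34 was 2.53 over genes with 30 to 100 reads and 18.5 over genes with 3000 to 30000 reads, as counting noise shrinks with depth. Depth limits genes under about 3 reads over the libraries, and levels of genes with shared sequence depend on a counting method that is not stated.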

Other observations

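The 4 gene lists, the tests of shared sequence and of GC content and length, and the genes of the last paragraph were chosen after values were seen, and the lymphocyte test was set before. Of 25 pattern recognition receptors and adaptors, 12 reached 1 FPKM. The kinase Tbk1 was at 30.1 FPKM, the transcription factor Irf3 at 21.9 FPKM, and the adaptors Myd88, Mavs and Ticam1 at 14.9, 13.2 and 10.5 FPKM. Of the Toll-like receptors, Tlr1 was highest at 5.74 FPKM, followed by Tlr3 at 2.90 FPKM, and Tlr5 and Tlr9 had 0 reads. Of 20 ligands of lymphocyte adhesion and costimulatory receptors, 7 reached 1 FPKM. Cd47, a ligand that restrains phagocytosis, was at 13.6 FPKM, Pvr at 9.70 FPKM and Nectin2 at 9.38 FPKM, whereas Icam1 was at 0.0196 FPKM and Cd86 had 0 reads.

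Of 17 smooth muscle and contractile genes, 13 reached 1 FPKM, with a median of 45.4 FPKM. Cnn2 was at 827 FPKM, Tpm1 at 291 FPKM and Actg2 at 45.4 FPKM. Lmod1 was at 7.18 FPKM, Smtn at 7.04 FPKM and Des at 4.69 FPKM. The 4 members under 1 FPKM were Myh11 (0.585 FPKM), Tagln (0.216 FPKM), Myl9 (0.0600 FPKM) and Cnn1 (0.0567 FPKM), so the list was not expressed as a whole. Of 23 collagen and matrix crosslinking genes, 20 reached 10 FPKM, with a median of 91.4 FPKM. The crosslinking enzyme Lox was at 526 FPKM, Timp2 at 517 FPKM and Sparc at 409 FPKM, and Eln had 0 reads.

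Loss of reads to near-identical genes as the cause of low epithelial markers beside mesenchymal and matrix genes would need widely shared sequence, and the median share of shared 31-base words over the 16 markers under 1 FPKM was 0.0177. The measure has limits, since Rpl35a was at 3.82 FPKM with 6.25% shared, and Krt8 with 39.0% shared stays uncertain. The levels of Epcam, Cdh1 and Col1a1 define the pattern, so they do not test a mixture of cells in general. Of the 18 epithelial markers, 16 were under 1 FPKM and 6 had 0 reads, whereas Jup and Tjp1 were above 1 FPKM. These levels argue against a sizeable part of RNA from cells that express most of the list. A mixture with cells of the line that lack these markers stays open. A mislabelled or exchanged culture and a state of the line stay open too, and no biological explanation was tested.

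Lymphocyte RNA in the control libraries was tested because the label names lymphocytes beside LA4 cells. It was predicted to give a median of at least 1 FPKM over the 36 T cell and B cell markers, and the median was 0 FPKM. That cut was not matched to a known share of lymphocytes, and a pooled median can miss RNA of T cells or B cells alone. However, none of the markers of either cell type reached 1 FPKM (highest 0.215 FPKM), and Ptprc was at 0 FPKM. These levels argue against a sizeable part of lymphocyte RNA in this column and leave a trace open. The reads of Il4 (3.30 FPKM) have no counterpart in Cd3e, which had 0 reads, and their source was not tested.

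Cholesterol biosynthesis genes lower in library 3 were picked for weighing because their 17 genes gave the value farthest below 0 among 72 pairs of list and library. After centring genes in bins of GC content and length the median difference was -0.50, whereas the same centring moved the MHC class I list in library 1 from -0.18 to -0.075. This argues against a bias by GC content or length as the whole cause. The library sizes tried differed too little to test library size as a cause. A wrong size would, however, shift all genes of library 3 together. The median over all genes there was 0.0043, and the cholesterol list lay below all 10000 random lists from the same library. These values argue against library size as the cause of the lower cholesterol genes. A difference in culture, such as density or medium, may lie behind the lower cholesterol genes in library 3. The labels name no such factor, and no biological explanation was tested.

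Of 4730 genes at 10 FPKM or more with library values, 127 lay 2-fold or more apart between libraries. Pseudogenes, short RNAs and genes with at least 10% shared 31-base words made up 87.4% of these and 24.5% of the other 4603. Genes outside these classes were ranked by range if protein-coding and not of the ribosomal, mitochondrial or predicted-gene classes. Among them the interferon-response gene Ifi27l2a and Atp5k had the widest ranges. Ifi27l2a was at 22.9, 34.7 and 8.88 FPKM in libraries 1, 2 and 3, and Atp5k at 31.3, 14.1 and 45.6 FPKM.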
